A study of Mus musculus with 16 samples.

How the data were processed

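Total RNA of skin from newborn pups was measured on 16 Illumina MouseRef-8 v2 arrays, 4 for each of WT, PSmut, RBPjmut and PSRmut. Per the labels' protocols, the pups were washed in saline and received no treatment, RNA was extracted with QIAzol and cleaned on RNeasy columns with DNase, checked on a Bioanalyser, and labelled and hybridized by the standard Illumina procedure with Cy3. The arrays were grouped by the genotype in their titles. Per the file headers, the deposited tables were exported from Illumina GenomeStudio, whose version is not given in the sources used here.

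The values used were the mean bead intensity of each probe in the deposited table without normalization or background subtraction. Its header names quantile normalization, but the medians of the arrays differ, so the values were treated as raw. The authors' second deposited table holds intensity that was quantile-normalized and background-subtracted, on a linear scale with negative values, and the deposited series values equal it (largest difference 0). Both tables hold a detection p-value for each probe and array, computed per the file headers by GenomeStudio and stepping in 798ths, which compares the probe with the negative control beads. The detection p-values of the 2 tables differ at 32 places.

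Intensities were background-corrected by normexp with the background estimated from the detection p-values, given an offset of 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3 and version 1.17.8 of data.table. Of 25697 probes, 14194 with a detection p under 0.05 on at least 4 of the 16 arrays were kept. For each gene the kept probe with the highest mean over all arrays was tested, which left 10713 genes, 2561 of them with more than 1 kept probe, and disagreeing probes of named genes are stated. Symbols were updated through the gene identifiers of the files with a RefSeq table of assembly GRCm38.p6, used for names only, which matched 23788 probes and 9927 of the tested genes; the other 786 keep the file's name. Probe coordinates are those of the files, whose genome build is not given in the sources used here.

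Probes without an identifier (422, of which 254 were kept) were joined to the gene with their symbol. This correction was made after results had been seen, because 207 symbols had been tested more than once, against the rule of 1 probe per gene. Without it 10920 genes were tested and 349, 322, 304 and 42 passed in PSmut, RBPjmut, PSRmut and the interaction, in place of 346, 318, 294 and 41, and 0 between mutants either way.

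A single linear model with 4 group means was fitted to all 16 arrays (lmFit and eBayes of limma, 12 residual and 4.16 prior degrees of freedom). It gave 7 comparisons: each mutant with WT, the 3 pairs of mutants, and the interaction, which is the difference of PSRmut and PSmut minus the difference of RBPjmut and WT. P-values were two-sided and adjusted by the method of Benjamini and Hochberg over the genes tested, and an adjusted p under 0.05 is called past the threshold. The median SE of a log2 fold change was 0.17, and 0.24 for the interaction. A probe not above background on any array of a group has only a bound there, given as at least N-fold, from the other group's mean against the higher, on each array, of the probe's own value and the lowest value among detected probes.

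The comparisons, tests, filters, 35 gene lists, alternatives and the rule for named genes were set before the data were examined. Named genes were the targeted genes, then the 6 largest rises and 6 largest falls against WT (4 and 4 for the interaction and the other comparisons) among genes past the threshold with non-overlapping arrays, without that condition for the interaction, then up to 2 members with the smallest adjusted p of each list with a member past the threshold. A called list without such a member gave the member with the largest fold change. Probes at background in both groups and genes without a symbol were skipped, and part of the genes so chosen are described. Names given outside the rule are marked as such.

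Gene lists were tested with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, adjusted over the 35 lists of a comparison. Camera with a correlation estimated from the data and fry were alternatives. The directional p of fry tests whether the genes of a list move one way on balance and its mixed p whether they change in either direction, and neither compares the list with other genes or lists. Members are counted past the threshold over all genes and adjusted over the list alone.

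Agreement between comparisons that share the WT arrays was set against 100 simulations of unchanged groups and repeated with the WT arrays divided. Calls near the targeted loci were tested with Fisher's exact test within 10 Mb, and 5 and 20 Mb as alternatives. The script was first tested on simulated data with 100 of 10713 genes changed by 1 on the log2 scale and 100 by 2. It called 89% and 100% of them for PSmut against WT, 79% and 98% for RBPjmut, 85% and 100% for PSRmut, and 62% and 96% for the interaction, with 8, 6, 16 and 8 false calls. Between mutants it called 78% and 99% (PSRmut and PSmut), 80% and 99% (PSRmut and RBPjmut) and 79% and 99% (PSmut and RBPjmut), with 12, 13 and 10 false calls.

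Alternatives tried were other background corrections, the authors' normalized table, median scaling, no or a stricter detection filter, every probe by itself, other variance models, array weights, only the groups compared, the replicate number as a block, sex-linked covariates, and leaving out each array. Further ones, chosen after the data were seen, left out sets of arrays that stood apart or took a Y-linked gene as covariate. Probes under the detection filter were left out of the main tests, and no array was.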

Results

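Total skin of newborn mice (postnatal day 0) was profiled on 16 Illumina MouseRef-8 v2 bead arrays. On these arrays 50-base probes on beads bind labelled RNA and are read as fluorescence intensity. The arrays fell into 4 genotype groups of 4 each. Wild-type littermates (WT) were the controls. Per the labels, PSmut skin was null for presenilin 1 and 2, RBPjmut for RBPj and PSRmut for all 3. Presenilins are the catalytic subunits of gamma-secretase, the protease that releases the intracellular part of Notch receptors. RBPj is the DNA-binding partner through which that part acts on its target genes. The median raw signal was 95.4 to 138 per array. Between 12770 and 13348 of the 25697 probes (49.7 to 51.9%) were above background on an array, at a detection p under 0.05. After normalization, arrays of the same group correlated at r of 0.966 to 0.995 and arrays of different groups at 0.969 to 0.991. These correlations are across probes, which are not independent replicates. After filtering, 14194 probes of 10713 genes were available. The labels call the arrays of a group replicates without saying that each came from a separate animal, so the p-values measure only the spread between these samples.

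The targeted genes gave a limited check of the labels. Of the Psen1 probes 1 was above background, at position 1806 of its transcript and without chromosome coordinates in the files. It read 7.38, 8.03, 8.38 and 8.11 on the 4 WT arrays (normalized log2 intensity) and 7.59, 7.62, 7.27 and 7.07 in PSmut skin. It read 8.22, 8.05, 7.19 and 8.01 in RBPjmut and 8.12, 7.09, 7.07 and 7.19 in PSRmut skin. The differences from WT were -0.59 (SE 0.27, adjusted p = 0.267) in PSmut, -0.11 (SE 0.27, adjusted p = 0.869) in RBPjmut and -0.61 (SE 0.27, adjusted p = 0.249) in PSRmut skin, none past the threshold. The library labelled PSRmut 1 lay with WT 2, 3 and 4. WT 1 and the library labelled RBPjmut 3 lay within the PSmut range. Every direction that uses these groups rests on the labels as deposited. The Psen2 probe lay at chromosome 1, 182157384 to 182157433, in a genome build not given in the sources used here. It differed from WT by 0.10 (adjusted p = 0.825), 0.16 (adjusted p = 0.654) and 0.08 (adjusted p = 0.865) in the 3 mutant groups. All 3 Rbpj probes and the other Psen1 probe (chromosome 12, 85029753 to 85029802) were at background on all 16 arrays. Whether any of these probes lies in the deleted part of its gene is not given in the sources used here. A probe outside that part checks nothing.

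**Figure D1:**
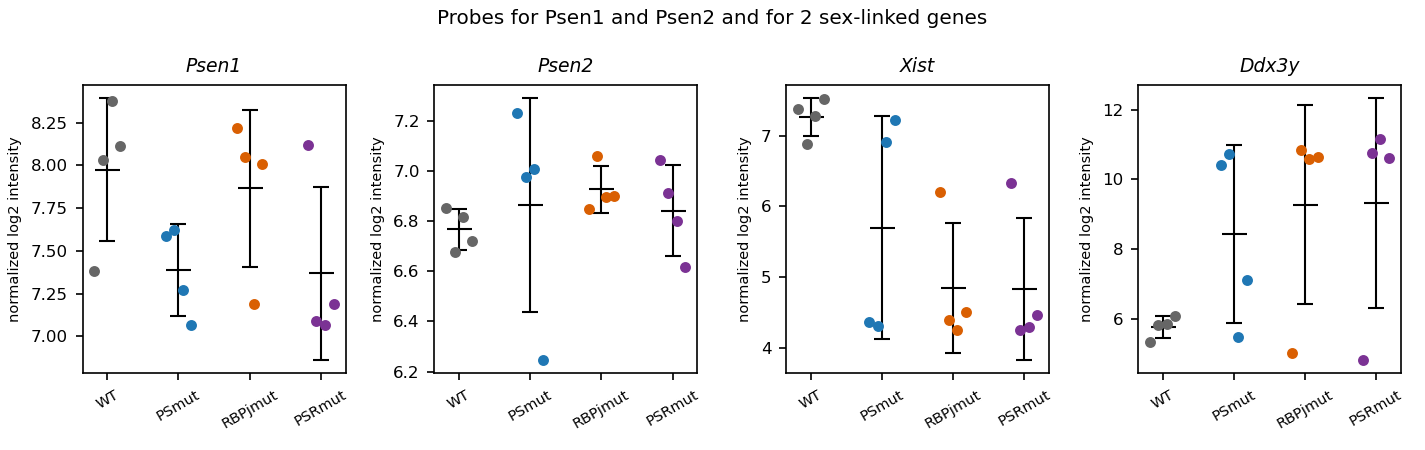
Normalized log2 intensity (y axis) of probes for Psen1, Psen2, Xist and Ddx3y on each array by genotype group (x axis), with 1 point per array and the mean with SD of 4 arrays. The Psen1 point of the library labelled PSRmut 1 (8.12) lies with most WT points. All WT arrays have high Xist (6.89 to 7.52). Of 12 mutant arrays, 8 have Xist of 4.25 to 4.51 and Ddx3y of 10.4 to 11.1.

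The labels do not give the sex of the pups. Xist, the RNA that coats the inactive X chromosome, read 6.89 to 7.52 on all 4 WT arrays, where the Y-linked Ddx3y read 5.34 to 6.09. Xist was also high in PSmut 3, PSmut 4, RBPjmut 1 and the library labelled PSRmut 1, with Ddx3y at 7.12 in PSmut 4. The other 8 mutant arrays had Ddx3y of 10.4 to 11.1 and Xist at background. In PSRmut skin Ddx3y differed from WT by 3.56 (SE 1.49, adjusted p = 0.22), which did not pass the threshold. The mean of the Y-linked genes was also tried as a covariate. With it the number of genes past the threshold against WT went from 346 to 233 in PSmut, from 318 to 94 in RBPjmut and from 294 to 102 in PSRmut skin.

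The comparison of PSmut with WT skin asks what loss of both presenilins changes. Krt6b, a keratin of injured and hyperproliferative epidermis, was 37-fold higher (log2 fold change 5.21, SE 1.00, adjusted p = 0.00783, n = 4 per group). Sprr2g, a small proline-rich precursor of the cornified envelope, was 28.2-fold higher (4.82, SE 0.51, adjusted p = 8.68e-05), with 3 of 4 WT arrays above background. Epgn, a ligand of the epidermal growth factor receptor, rose by 3.72 (SE 0.35, adjusted p = 8.68e-05). The serine protease Klk6 rose by 3.91 (SE 0.59, adjusted p = 0.00154) and the serine protease inhibitor Serpinb2 by 3.49 (SE 0.36, adjusted p = 8.68e-05). Sprr4 rose by 4.32 (SE 0.96, adjusted p = 0.0204), with 3 of 4 WT arrays above background. Sprr4 no longer passed without WT 1 or 2 or PSmut 1 or 2 (adjusted p up to 0.0747). Among the genes that fell, the galectin Lgals4 was at -2.20 (SE 0.35, adjusted p = 0.00219), although its second probe read -0.21. The retinol-oxidizing Adh1 was at -1.96 (SE 0.32, adjusted p = 0.00269). Cyp2b19, a keratinocyte cytochrome P450, was 3.6-fold lower (-1.85, SE 0.22, adjusted p = 0.000204).

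**Figure D2:**
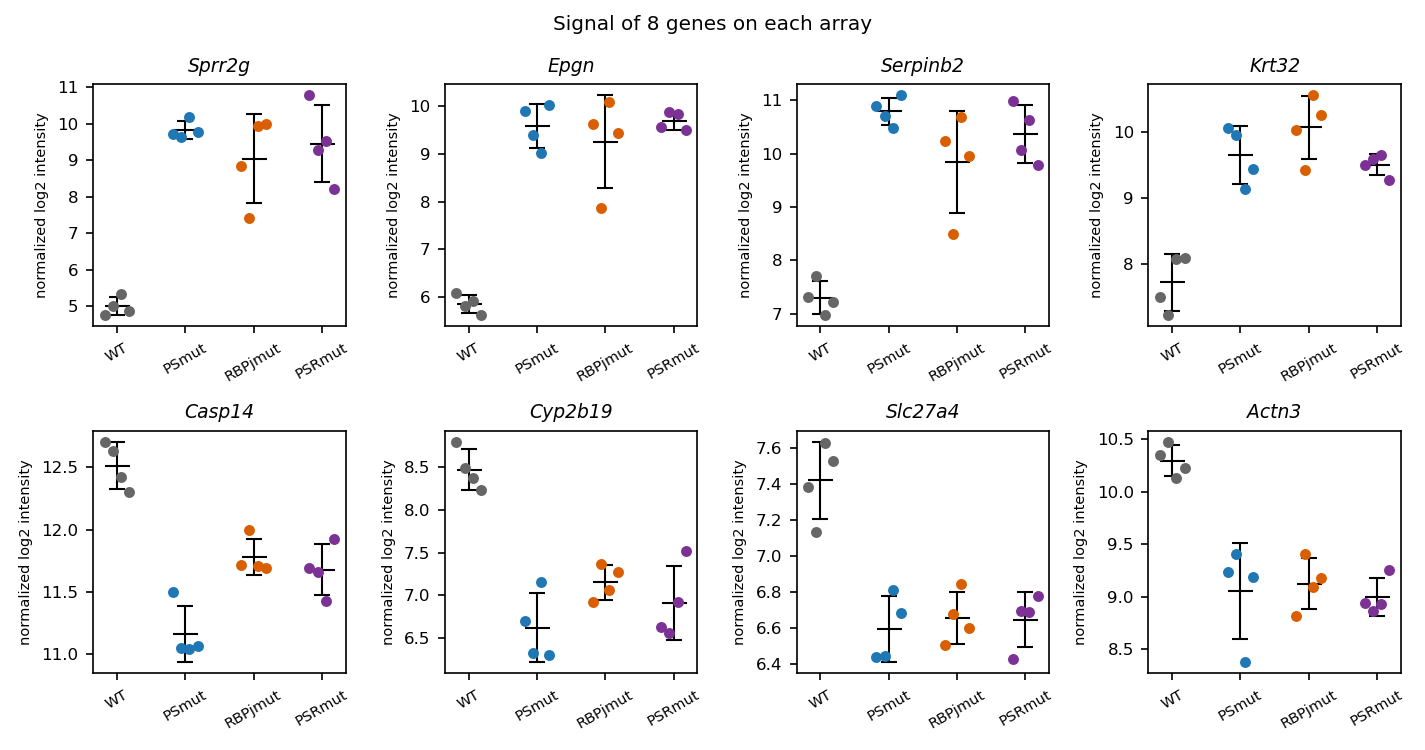
Normalized log2 intensity (y axis) of 8 genes on each array by genotype group (x axis), with 1 point per array and the mean with SD of 4 arrays. Sprr2g, Epgn, Serpinb2 and Krt32 are higher on every mutant array than on every WT array, and Casp14, Cyp2b19, Slc27a4 and Actn3 are lower on every mutant array.

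Of the 35 gene lists fixed before the data were examined, 12 were called in PSmut skin, 6 higher and 6 lower. List medians are medians of the log2 fold changes of the measured members. Counts are over all genes unless adjusted over the list alone, and where 1 direction is given 0 passed in the other. The list of epidermal stress and alarmin genes had 11 of 23 higher, and 16 higher adjusted over the list alone. Camera at median 1.15 gave adjusted p = 3.47e-13, and adjusted p = 0.0344 with an estimated correlation. S100a8 and S100a9, the subunits of calprotectin, rose by 2.03 (SE 0.29, adjusted p = 0.000897) and 2.22 (SE 0.30, adjusted p = 0.000693). Both also stand in the neutrophil list. That list had 3 of 9 higher, and 5 higher adjusted over the list alone. At median 0.84, camera gave adjusted p = 2.96e-06 and adjusted p = 0.0252 with an estimated correlation. Barrier-lipid genes had 7 of 15 lower and 1 higher, and 11 lower and 1 higher adjusted over the list alone. Median -0.53 gave camera adjusted p = 1.62e-08, and adjusted p = 0.0124 with an estimated correlation. Slc27a4, a fatty acid transporter, was at -0.83 (SE 0.13, adjusted p = 0.00231). Cyp4f39, a fatty acid hydroxylase of ceramide synthesis, was at -0.86 (SE 0.15, adjusted p = 0.00354). Hair shaft, matrix and cortex genes had 5 of 27 higher, and 13 higher adjusted over the list alone. With median 1.05, camera gave adjusted p = 3.89e-12, and adjusted p = 0.289 with an estimated correlation. The hair keratin Krt32 rose by 1.94 (SE 0.26, adjusted p = 0.000544). Krt84, another hair keratin, was above background on no WT array and at least 1.53-fold higher in PSmut skin (adjusted p = 0.00965). The granular and cornified layer list went both ways and was not called. It had 11 of 39 higher and 4 lower, and 14 higher and 11 lower adjusted over the list alone. Camera at median 0.15 gave adjusted p = 0.108, and adjusted p = 0.637 with an estimated correlation. The mixed test of fry gave adjusted p = 1.25e-07. Casp14, a protease of filaggrin breakdown, was at -1.36 (SE 0.14, adjusted p = 8.68e-05) while Sprr2g and Sprr4 of the same list rose.

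Basal keratinocyte genes had 3 of 15 higher, and 6 higher adjusted over the list alone. At median 0.32, camera gave adjusted p = 0.00154 and adjusted p = 0.174 with an estimated correlation. Lamc2, a laminin chain of the basement membrane, rose by 0.92 (SE 0.16, adjusted p = 0.00336), with 0.48 and 0.97 by its other two probes. Sebaceous gland genes had 2 of 9 lower, and 3 lower adjusted over the list alone. Median -0.37 gave camera adjusted p = 0.0358, and adjusted p = 0.232 with an estimated correlation. Adjusted p reached 0.0883 and the call was lost without WT 3 or 4 or PSmut 3. The median was -0.18 without WT 3. Scd1, a fatty acid desaturase of that list, was at -1.32 (adjusted p = 0.0285). Scd1 no longer passed without WT 3 or 4 or any PSmut array (adjusted p up to 0.0888). Markers of other cell types of whole skin were also called lower. Dermal fibroblast and matrix genes had 2 of 23 lower, and 4 lower adjusted over the list alone. With median -0.20, camera gave adjusted p = 0.0101, and adjusted p = 0.582 with an estimated correlation. The median was -0.13 without PSmut 1. The microfibril gene Mfap5 was at -1.16 (SE 0.16, adjusted p = 0.000897). Skeletal muscle genes had 1 of 25 lower, and 4 lower adjusted over the list alone. Camera at median -0.13 gave adjusted p = 0.00538, and adjusted p = 0.502 with an estimated correlation. Adjusted p reached 0.0837 and the call was lost without PSmut 3. The median was -0.09 without WT 2 and -0.20 without WT 3. The fast-fibre actinin Actn3 was at -1.24 (SE 0.19, adjusted p = 0.0016). Schwann cell genes had 1 of 10 lower, and 4 lower adjusted over the list alone. At median -0.32, camera gave adjusted p = 0.00824 and adjusted p = 0.174 with an estimated correlation. The myelin gene Mbp was at -1.01 (adjusted p = 0.00504), while its other probes read -0.26 and 0.01. Vascular genes had 0 of 20 past the threshold, and 3 lower adjusted over the list alone. Median -0.26 gave camera adjusted p = 0.00356, and adjusted p = 0.367 with an estimated correlation. The endothelial receptor Robo4 was at -0.77 (adjusted p = 0.0611). Interferon-stimulated genes had 0 of 19 past the threshold, and 0 adjusted over the list alone. With median 0.29, camera gave adjusted p = 0.0117, and adjusted p = 0.533 with an estimated correlation. The median was 0.48 without PSmut 3. Isg15 was at 0.99 (adjusted p = 0.223). Wnt pathway genes had 0 of 22 past the threshold, and 1 higher adjusted over the list alone. Camera at median 0.10 gave adjusted p = 0.0478, and adjusted p = 0.367 with an estimated correlation. Adjusted p reached 0.173 and the call was lost without WT 1, 2 or 3, PSmut 3 or 4 or PSRmut 3. Wnt10a was at 0.87 (adjusted p = 0.059). Cd3g, a T cell receptor subunit, was above background on all 4 WT and no PSmut arrays. It was at least 1.5-fold lower (adjusted p = 0.00302).

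In PSmut skin limma called 346 genes against WT at an adjusted p under 0.05. Of these 141 were higher (65 at least 2-fold) and 205 lower (65 at least 2-fold). The arrays of the 2 groups did not overlap for 1383 genes (12.9%), where chance gives 2.86%. Median and mean differed in sign for inner root sheath genes. Each array was also scaled to the same median in place of quantile normalization. That called 300 genes, 27.3% of them higher where quantile normalization gave 40.8%. It put the median of all genes at -0.11 where quantile normalization put it at -0.02, and the changes given here are relative to that shift. The count was 167 without WT 1, 190 without WT 2, 225 without WT 4, 215 without PSmut 1 and 191 without PSmut 2. Array weights gave 1303. Without WT 1 and WT 2 together the count was 71, and without WT 3 and WT 4 together 203, sets of arrays chosen after the data were seen. Of the genes named here, the authors' table ended the calls of Krt84 (0.174) and Cd3g (0.0667) and no filter that of Scd1 (0.0525), adjusted p in brackets. Krt84 was at 0.33 without background correction, still past the threshold.

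RBPjmut skin was compared with WT to ask what loss of RBPj changes. Sprr2g was 16.5-fold higher (log2 fold change 4.05, SE 0.51, adjusted p = 0.000815, n = 4 per group), with 3 of 4 WT arrays above background. Epgn was 10.5-fold higher (3.39, SE 0.35, adjusted p = 0.00018) and Klk6 8.54-fold higher (3.10, SE 0.59, adjusted p = 0.0114). Krtap1-5, a keratin-associated protein of the hair cortex, rose by 3.11 (SE 0.39, adjusted p = 0.000818), with 3 of 4 WT arrays above background. LOC100039728 rose by 2.96 (SE 0.53, adjusted p = 0.00709). Small proline-rich, late cornified envelope and keratin-associated protein genes have near-identical copies. Which copy a probe of these families read is uncertain throughout. Lower genes included Abra, a muscle actin-binding protein, at -1.84 (SE 0.28, adjusted p = 0.0024). The heme oxygenase Hmox1 was at -1.68 (SE 0.33, adjusted p = 0.0146) and the growth factor Btc at -1.45 (SE 0.23, adjusted p = 0.00389).

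Camera called 12 lists in RBPjmut skin, 7 higher and 5 lower, and 0 of the 12 calls held with an estimated correlation. Hair shaft, matrix and cortex genes had 12 of 27 higher, and 19 higher adjusted over the list alone. At median 1.53, camera gave adjusted p = 1.15e-18 and adjusted p = 0.281 with an estimated correlation. Krt32 was at 2.36 (SE 0.26, adjusted p = 0.000268). Granular and cornified layer genes had 10 of 39 higher and 1 lower, and 15 higher and 2 lower adjusted over the list alone. Median 0.20 gave camera adjusted p = 1.81e-05, and adjusted p = 0.31 with an estimated correlation. The median was 0.06 without the library labelled RBPjmut 3. Lce3c, a late cornified envelope gene, was at 2.36 (SE 0.35, adjusted p = 0.00197). Stress and alarmin genes had 4 of 23 higher, and 8 higher adjusted over the list alone. With median 0.64, camera gave adjusted p = 3.51e-08, and adjusted p = 0.243 with an estimated correlation. Tslp, an epithelial cytokine, was above background on no WT array and at least 1.86-fold higher (adjusted p = 0.00505). The protease inhibitor Slpi was at 1.96 (adjusted p = 0.0141), with 2 of 4 WT arrays above background. Neutrophil genes had 1 of 9 higher, and 2 higher adjusted over the list alone. Camera at median 0.39 gave adjusted p = 0.0154, and adjusted p = 0.281 with an estimated correlation. Adjusted p reached 0.0831 and the call was lost without the library labelled RBPjmut 3. The 1 that passed was S100a8 at 1.13 (adjusted p = 0.0467). S100a8 no longer passed without WT 1, 3 or 4, PSmut 1 or 4, RBPjmut 1 or 4, the library labelled RBPjmut 3 or PSRmut 2 or 3 (adjusted p up to 0.152). Melanocyte genes had 1 of 10 higher, and 6 higher and 1 lower adjusted over the list alone. At median 0.60, camera gave adjusted p = 0.00231 and adjusted p = 0.31 with an estimated correlation. The pigment enzyme Dct was at 0.78 (adjusted p = 0.021). Dct no longer passed without WT 2 or 4, RBPjmut 1 or 4 or the library labelled RBPjmut 3 (adjusted p up to 0.0718).

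In RBPjmut skin barrier-lipid genes were called lower. They had 2 of 15 lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone. Median -0.37 gave camera adjusted p = 0.00161, and adjusted p = 0.243 with an estimated correlation. Slc27a4 was at -0.77 (SE 0.13, adjusted p = 0.00603). Cholesterol synthesis genes had 1 of 17 higher, and 5 higher and 1 lower adjusted over the list alone. With median 0.36, camera gave adjusted p = 0.0281, and adjusted p = 0.553 with an estimated correlation. Without the library labelled RBPjmut 3, this call was lost (adjusted p up to 0.195). The median was 0.15 without the library labelled RBPjmut 3. Nsdhl was at 1.19 (adjusted p = 0.00874), with 0.24 to 1.36 by its other probes. Unfolded protein response genes had 2 of 17 higher and 1 lower, and 2 higher and 2 lower adjusted over the list alone. Camera at median 0.27 gave adjusted p = 0.0444, and adjusted p = 0.31 with an estimated correlation. Adjusted p reached 0.155 and the call was lost without WT 1 or 4, RBPjmut 2, the library labelled RBPjmut 3 or the library labelled PSRmut 1. The chaperone Calr was at 1.35 (adjusted p = 0.00897). Dermal genes had 1 of 23 lower, and 3 lower adjusted over the list alone. At median -0.27, camera gave adjusted p = 0.00107 and adjusted p = 0.409 with an estimated correlation. Mfap5 was at -0.87 (adjusted p = 0.0104). Muscle genes had 1 of 25 lower, and 6 lower adjusted over the list alone. Median -0.24 gave camera adjusted p = 0.00562, and adjusted p = 0.45 with an estimated correlation. Adjusted p reached 0.0609 and the call was lost without the library labelled RBPjmut 3. Actn3 was at -1.17 (adjusted p = 0.004). Vascular genes had 0 of 20 past the threshold, and 6 lower adjusted over the list alone. With median -0.25, camera gave adjusted p = 0.00271, and adjusted p = 0.336 with an estimated correlation. The endothelial receptor Tie1 was at -0.79 (adjusted p = 0.0654). Schwann cell genes had 1 of 10 lower, and 1 lower adjusted over the list alone. Camera at median -0.26 gave adjusted p = 0.0185, and adjusted p = 0.281 with an estimated correlation. Adjusted p reached 0.061 and the call was lost without RBPjmut 2 or the library labelled RBPjmut 3. Mbp was at -0.85 (adjusted p = 0.0221), with 0.04 and -0.29 by its other two probes. Mbp no longer passed without WT 1 or 2 or RBPjmut 4 (adjusted p up to 0.0745). Cd3g was above background on all 4 WT and no RBPjmut arrays and at least 1.48-fold lower (adjusted p = 0.00476).

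By limma 318 genes passed the threshold in RBPjmut skin, 156 higher (66 at least 2-fold) and 162 lower (34 at least 2-fold). Arrays did not overlap for 1424 genes (13.3%), against 2.86% by chance. Median, mean or test differed in sign for spinous keratinocyte (median -0.02, mean 0.12), gamma-secretase, outer root sheath, proliferation, lysosome, Merkel cell and erythroid genes. Median scaling called 225 genes, 38.7% of them higher where quantile normalization gave 49.1%. The count was 98 without WT 1, 118 without WT 2, 159 without WT 4, 132 without RBPjmut 1 and 519 without RBPjmut 2. It was 210 without the library labelled RBPjmut 3 and 148 without RBPjmut 4. Without the libraries labelled RBPjmut 3 and PSRmut 1 it was 254. With array weights it was 947, and with the Y-linked mean as covariate 94. Of the alternatives chosen after the data were seen, Ddx3y as covariate gave 97 and the 8 high-Xist arrays alone 30. Without WT 1 and WT 2 together it was 27, and without WT 3 and WT 4 together 161. Of the genes named here, the authors' table ended the calls of Tslp (0.0697) and Cd3g (0.0658), adjusted p in brackets. The Y-linked mean ended those of LOC100039728 (0.0505), Hmox1 (0.0757), Slpi (0.0524), Dct (0.0573), Nsdhl (0.0601), Calr (0.0506) and Mbp (0.0751), and median scaling also that of Dct. S100a8 was lost under 5 alternatives (adjusted p up to 0.102).

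PSRmut skin is labelled null for both presenilins and RBPj together. Sprr2g was 21.8-fold higher (log2 fold change 4.45, SE 0.51, adjusted p = 0.00039, n = 4 per group), with 3 of 4 WT arrays above background. Epgn was 14.3-fold higher (3.83, SE 0.35, adjusted p = 6.38e-05). Klk6 rose by 3.45 (SE 0.59, adjusted p = 0.00523) and Serpinb2 by 3.06 (SE 0.36, adjusted p = 0.000458). The genes with large falls included Oas1f at -1.76 (SE 0.22, adjusted p = 0.000577) and Adh1 at -1.70 (SE 0.32, adjusted p = 0.01). Lgals4 was at -1.67 (adjusted p = 0.0171), with -0.19 by its second probe. Lgals4 no longer passed without WT 1 or 2 or PSRmut 2 or 3 (adjusted p up to 0.0627). Bbox1, the last enzyme of carnitine synthesis, was 2.97-fold lower (-1.57, SE 0.22, adjusted p = 0.00146). Cyp2b19 was 2.95-fold lower (-1.56, SE 0.22, adjusted p = 0.00146).

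In PSRmut skin 15 lists were called, 9 higher and 6 lower, of which the barrier-lipid and neutrophil calls held with an estimated correlation. Barrier-lipid genes had 5 of 15 lower and 1 higher, and 10 lower and 1 higher adjusted over the list alone. At median -0.49, camera gave adjusted p = 3.1e-06 and adjusted p = 0.0286 with an estimated correlation. Slc27a4 was at -0.78 (adjusted p = 0.00523). Neutrophil genes had 3 of 9 higher, and 3 higher adjusted over the list alone. Median 0.77 gave camera adjusted p = 3.76e-06, and adjusted p = 0.0286 with an estimated correlation. The median was 0.50 without PSRmut 2. Stress and alarmin genes had 6 of 23 higher, and 12 higher adjusted over the list alone. With median 0.76, camera gave adjusted p = 2.63e-10, and adjusted p = 0.0759 with an estimated correlation. S100a9 and S100a8, which stand in both lists, were at 2.01 (adjusted p = 0.00182) and 1.92 (adjusted p = 0.00191). Granular and cornified layer genes had 8 of 39 higher and 1 lower, and 14 higher and 1 lower adjusted over the list alone. Camera at median 0.25 gave adjusted p = 2.24e-06, and adjusted p = 0.267 with an estimated correlation. The median was 0.13 without WT 2. Sprr2h was at 1.86 (adjusted p = 0.00172), with 3 of 4 WT arrays above background. Hair shaft, matrix and cortex genes had 2 of 27 higher, and 10 higher adjusted over the list alone. At median 0.88, camera gave adjusted p = 6.39e-09 and adjusted p = 0.352 with an estimated correlation. Krt32 was at 1.79 (adjusted p = 0.00146). Basal keratinocyte genes had 1 of 15 higher, and 1 higher and 1 lower adjusted over the list alone. Median 0.23 gave camera adjusted p = 0.0413, and adjusted p = 0.352 with an estimated correlation. Adjusted p reached 0.0887 and the call was lost without WT 3, PSRmut 4 or the library labelled PSRmut 1. Lamc2 was at 0.78 (adjusted p = 0.0156), with 0.39 and 0.80 by its other two probes. Sebaceous gland genes had 1 of 9 lower, and 4 lower adjusted over the list alone. With median -0.42, camera gave adjusted p = 0.0113, and adjusted p = 0.134 with an estimated correlation. The median was -0.25 without WT 3 and -0.23 without PSRmut 4.

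Markers of other cell types were also called lower in PSRmut skin. Muscle genes had 1 of 25 lower, and 7 lower adjusted over the list alone. Camera at median -0.21 gave adjusted p = 0.000891, and adjusted p = 0.36 with an estimated correlation. Actn3 was at -1.30 (adjusted p = 0.00172). Schwann cell genes had 1 of 10 lower, and 1 lower adjusted over the list alone. At median -0.34, camera gave adjusted p = 0.0089 and adjusted p = 0.15 with an estimated correlation. Mbp was at -1.01 (adjusted p = 0.00768), with 0.13 and -0.19 by its other two probes. Dermal genes had 1 of 23 lower, and 1 lower adjusted over the list alone. Median -0.20 gave camera adjusted p = 0.0437, and adjusted p = 0.617 with an estimated correlation. Adjusted p reached 0.361 and the call was lost without WT 1 or 2, PSRmut 3 or the library labelled PSRmut 1. The median was -0.11 without the library labelled PSRmut 1. Mfap5 was at -0.80 (adjusted p = 0.0157). Mfap5 no longer passed without WT 1 or 2 (adjusted p up to 0.0624). Vascular genes had 0 of 20 past the threshold, and 0 adjusted over the list alone. With median -0.19, camera gave adjusted p = 0.0387, and adjusted p = 0.506 with an estimated correlation. Without WT 1, PSRmut 2 or 4 or the library labelled PSRmut 1, this call was lost (adjusted p up to 0.147). The tight junction gene Cldn5 was at -0.52 (adjusted p = 0.192). Some lists were called higher without a member past the threshold. Immediate early genes had 0 of 16 past the threshold, and 0 adjusted over the list alone. Camera at median 0.40 gave adjusted p = 0.00711, and adjusted p = 0.433 with an estimated correlation. The median was 0.67 without the library labelled PSRmut 1 and 0.25 without PSRmut 2. Socs3 was at 0.90 (adjusted p = 0.17). Hedgehog genes had 0 of 6 past the threshold, and 0 adjusted over the list alone. At median 0.32, camera gave adjusted p = 0.0266 and adjusted p = 0.134 with an estimated correlation. Without PSRmut 2, this call was lost (adjusted p up to 0.0721). Shh was at 0.86 (adjusted p = 0.345). Wnt pathway genes had 0 of 22 past the threshold, and 0 adjusted over the list alone. Median 0.15 gave camera adjusted p = 0.023, and adjusted p = 0.271 with an estimated correlation. Adjusted p reached 0.11 and the call was lost without PSRmut 3. Wnt10a was at 0.63 (adjusted p = 0.177). Y-linked genes had 0 of 3 past the threshold, and 2 higher adjusted over the list alone. With median 0.64, camera gave adjusted p = 0.0413, and adjusted p = 0.271 with an estimated correlation. Without WT 1 or 4 or PSRmut 2, 3 or 4, this call was lost (adjusted p up to 0.0885). Cd3g was above background on all 4 WT and no PSRmut arrays and at least 1.49-fold lower (adjusted p = 0.00578).

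**Figure D3:**
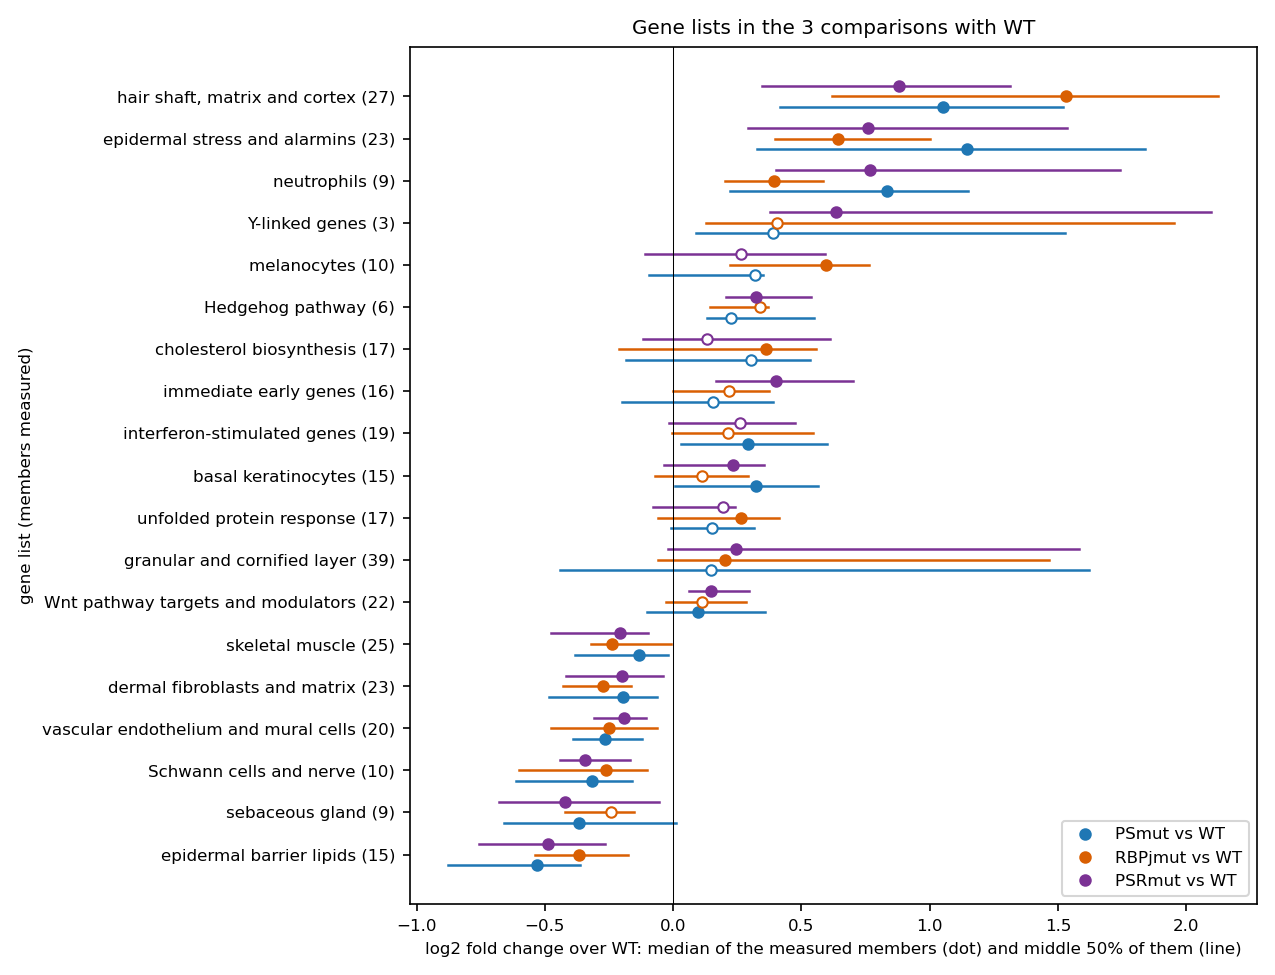
Log2 fold change over WT (x axis) of the gene lists called in at least 1 of the 3 comparisons with WT (y axis, with members measured), the dot being the median of the members, the line their middle 50% and a filled dot a camera call. Hair shaft, matrix and cortex genes have medians of 1.05, 1.53 and 0.88 in PSmut, RBPjmut and PSRmut skin, and barrier-lipid genes of -0.53, -0.37 and -0.49.

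By limma 294 genes passed the threshold in PSRmut skin, 124 higher (49 at least 2-fold) and 170 lower (48 at least 2-fold). Arrays did not overlap for 1392 genes (13.0%), against 2.86% by chance. Median, mean or test differed in sign for spinous, inner and outer root sheath, proliferation, macrophage and erythroid genes. Median scaling called 232 genes, 24.6% of them higher where quantile normalization gave 42.2%. It put the median of all genes at -0.12 where quantile normalization put it at -0.03. The count was 112 without WT 1, 148 without WT 2, 187 without WT 3 and 160 without WT 4. It was 185 without the library labelled PSRmut 1 and 163 without PSRmut 2. Without the libraries labelled RBPjmut 3 and PSRmut 1 it was 208. Array weights gave 945 and the Y-linked mean as covariate 102. Ddx3y as covariate, chosen after the data were seen, gave 115. Without WT 1 and WT 2 together the count was 46, and without WT 3 and WT 4 together 168. The call of Cd3g (0.0702) ended with the authors' table, of Lamc2 (0.0794) with median scaling and of Adh1 (0.108) with the Y-linked mean, adjusted p in brackets.

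No single Notch target, receptor, ligand or partner was past the threshold in the 3 comparisons with WT. Of 13 measured Notch targets 0 passed, with medians of -0.09, -0.05 and 0.11 in PSmut, RBPjmut and PSRmut skin (camera adjusted p = 0.445, 0.736 and 0.774). Adjusted over the list alone, 1, 0 and 0 fell. Of 18 receptors, ligands and partners 0 passed, with medians of -0.002, -0.13 and -0.10 (camera adjusted p = 0.323, 0.176 and 0.317). For these genes 2, 0 and 0 fell when adjusted over the list alone. The mixed test of fry, for change in either direction, gave adjusted p = 0.000151, 0.00368 and 0.0246 for this list, and 0.243, 0.0199 and 0.297 for the targets. It gave 0.00575, 0.0417 and 0.024 for gamma-secretase and related proteases and 0.0712, 0.102 and 0.231 for its substrates. That test passed for 24, 21 and 17 of the 35 lists. Notch3 was at -0.63, -0.52 and -0.49 (adjusted p = 0.0655, 0.122 and 0.155). Notch1 was at -0.58, -0.52 and -0.45 (adjusted p = 0.0844, 0.117 and 0.192), and both were named after their values were seen. Among 20 substrates of gamma-secretase other than Notch, 0 passed over all genes or over the list alone. The list of gamma-secretase and presenilin-family proteases had 1, 1 and 0 of 9 lower, with medians of -0.10, 0.11 and -0.12 (camera adjusted p = 0.451, 0.951 and 0.506). Adjusted over that list alone, 2, 1 and 1 fell. Sppl3, an intramembrane protease related to presenilin, was at -0.40 (adjusted p = 0.0489) in PSmut, -0.42 (adjusted p = 0.0424) in RBPjmut and -0.37 (adjusted p = 0.0801) in PSRmut skin, the last not past the threshold. In PSmut skin it no longer passed without any WT array, PSmut 1, 2 or 4, RBPjmut 1, the library labelled RBPjmut 3 or any PSRmut array (adjusted p up to 0.129). In RBPjmut skin it no longer passed without any WT array, PSmut 2, RBPjmut 1, the library labelled RBPjmut 3 or PSRmut 3 (adjusted p up to 0.121). Other alternatives set beforehand ended these calls too, 5 and 4 of them (adjusted p up to 0.111 and 0.223).

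The 3 comparisons with WT were set against each other to ask how far the lesions changed the same genes. Of 559 genes past the threshold in at least 1 comparison, 143 passed in all 3, 61 higher and 82 lower. A further 113 passed in exactly 2 and 303 in exactly 1, and 554 of the 559 had the same direction in all 3. Among those in all 3, Sprr2g (mean log2 fold change 4.44), Epgn (3.65), Klk6 (3.49) and Serpinb2 (3.03) had the largest rises. Lgals4 (-1.76), Adh1 (-1.63), Oas1f (-1.61) and Cyp2b19 (-1.58) had the largest falls. PSmut and RBPjmut shared 80 higher and 101 lower calls, where independent lists of these sizes would share 2.05 and 3.1. PSmut and PSRmut shared 76 and 113 (1.63 and 3.25 if independent), and RBPjmut and PSRmut 79 and 93 (1.81 and 2.57). There were 0 calls of opposite direction. Fold changes correlated at r of 0.822, 0.857 and 0.836 in these 3 pairs, across genes, which are not independent replicates. In 100 simulations of unchanged groups against the same 4 WT arrays r was 0.502, 0.5 and 0.499, and at most 0.01 calls were shared. Covariance was 0.103, 0.104 and 0.0988 (simulated 0.0225, 0.0224 and 0.0223), and net of WT noise 0.0804, 0.0811 and 0.0765. A shift common to the WT arrays stays in. The WT arrays were also split 2 and 2 in the 6 ways, sharing any such shift but no control. Then r was 0.558 to 0.698, 0.552 to 0.724 and 0.546 to 0.701. The pairs shared 7 to 14, 8 to 18 and 8 to 16 higher calls and 13 to 33, 18 to 36 and 10 to 23 lower calls.

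**Figure D4:**
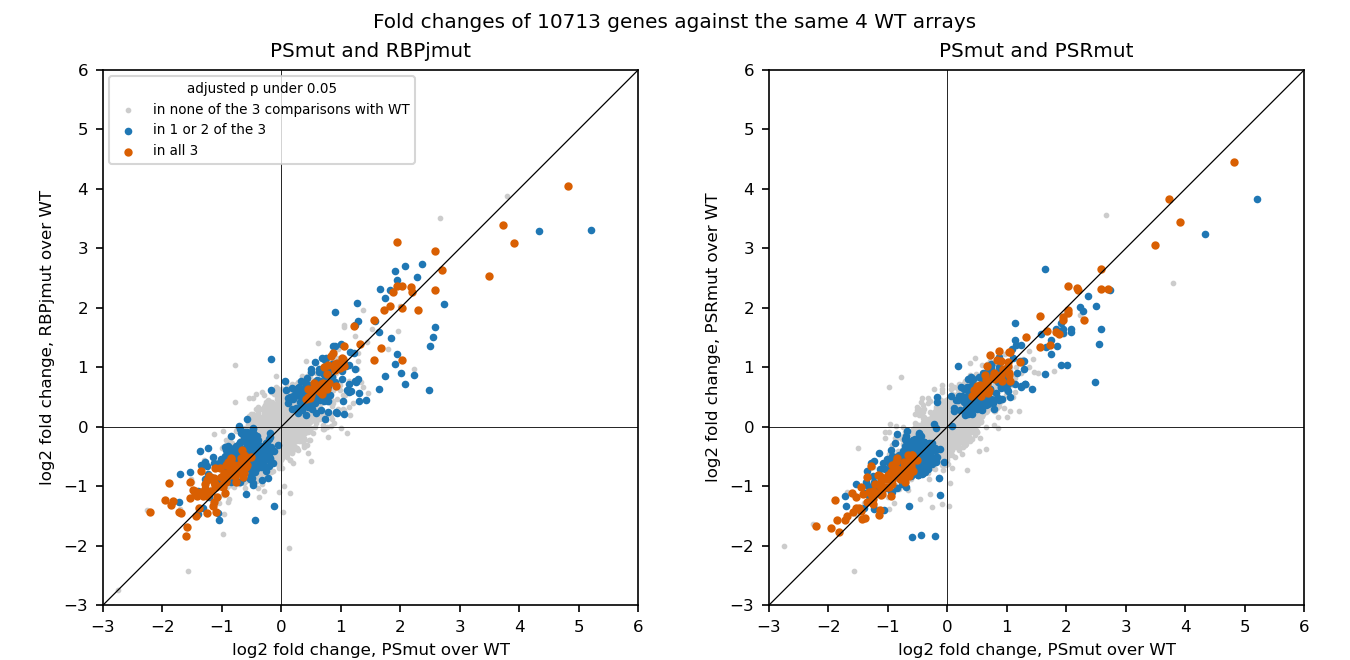
Log2 fold change over WT of 10713 genes, 1 point per gene, in PSmut skin (x axis) against RBPjmut skin (left panel, y axis) and PSRmut skin (right panel, y axis), coloured by the number of comparisons with WT in which the gene passed the threshold, with the line of equal change. The genes past the threshold in all 3 lie near that line in both panels (r over all genes 0.822 and 0.857), and both axes use the same WT arrays.

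The mutant groups were compared with each other to ask what losing RBPj adds to presenilin loss and the reverse. Limma called 0 genes for PSRmut against PSmut (375 at an unadjusted p under 0.05, smallest adjusted p = 0.396). It called 0 for PSRmut against RBPjmut (403, smallest adjusted p = 0.997) and 0 for PSmut against RBPjmut (537, smallest adjusted p = 0.302). Arrays did not overlap for 186 (1.74%), 193 (1.80%) and 238 genes (2.22%), under the 2.86% of chance. Psen1 differed by -0.02 (95% interval -0.59 to 0.55), -0.50 (95% interval -1.07 to 0.07) and -0.48 (95% interval -1.05 to 0.09). Other settings called 0 as well, with these exceptions. A trended and robust variance called 2 genes for PSmut against RBPjmut, the 8 high-Xist arrays alone 1, 1 and 3 genes, and the arrays without the libraries labelled RBPjmut 3 and PSRmut 1 gave 3, 1 and 3. With the labels of these 2 libraries exchanged, 208 genes passed for PSRmut against RBPjmut, so the 0 rests on the labels as deposited. Simulation called 78 to 80% of changes of 1 (log2) and 99% of 2. Power for fewer changed genes or other noise was not tested.

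Some gene lists were called between mutants, with 0 members past the threshold over all genes. None of these calls held with an estimated correlation or by the directional test of fry. For PSRmut against PSmut skin 4 lists were called. Granular and cornified layer genes had 5 higher adjusted over the list alone. Camera at median 0.15 gave adjusted p = 1.12e-06, and adjusted p = 0.675 with an estimated correlation. The median was 0.30 without PSRmut 4. Spinous keratinocyte genes had 2 higher adjusted over the list alone. At median 0.10, camera gave adjusted p = 0.0219 and adjusted p = 0.675 with an estimated correlation. Without PSmut 4 or the library labelled PSRmut 1, this call was lost (adjusted p up to 0.25). Basal keratinocyte genes had 0 past the threshold adjusted over the list alone. Median -0.14 gave camera adjusted p = 0.0496, and adjusted p = 0.675 with an estimated correlation. Adjusted p reached 0.466 and the call was lost without any WT array, PSmut 3 or 4, RBPjmut 1, the library labelled RBPjmut 3 or PSRmut 2 or 3. The median was -0.06 without PSmut 3, -0.07 without PSmut 4 and -0.08 without PSRmut 2. Proliferation genes had 0 past the threshold adjusted over the list alone. With median -0.13, camera gave adjusted p = 0.0219, and adjusted p = 0.953 with an estimated correlation. Without PSmut 1 or 2, PSRmut 3 or the library labelled PSRmut 1, this call was lost (adjusted p up to 0.619). The median was -0.06 without PSmut 1, -0.22 without PSmut 4, -0.04 without the library labelled PSRmut 1 and -0.24 without PSRmut 4. For PSRmut against RBPjmut skin 2 were called. Hair shaft genes had 0 past the threshold adjusted over the list alone. Camera at median -0.57 gave adjusted p = 8.81e-10, and adjusted p = 0.699 with an estimated correlation. The median was -1.01 without RBPjmut 2, -0.31 without the library labelled RBPjmut 3 and -0.35 without PSRmut 4. Neutrophil genes had 3 higher adjusted over the list alone. At median 0.38, camera gave adjusted p = 0.000299 and adjusted p = 0.163 with an estimated correlation. The median was 0.19 without PSRmut 2 and 0.61 without PSRmut 4. For PSmut against RBPjmut skin 9 were called. Neutrophil genes had 2 higher adjusted over the list alone. Median 0.43 gave camera adjusted p = 0.000153, and adjusted p = 0.0848 with an estimated correlation. Stress and alarmin genes had 3 higher adjusted over the list alone. With median 0.21, camera gave adjusted p = 0.00169, and adjusted p = 0.487 with an estimated correlation. Without RBPjmut 2, this call was lost (adjusted p up to 0.223). The median was 0.38 without PSmut 1, 0.36 without PSmut 3 and 0.36 without the library labelled RBPjmut 3. Basal keratinocyte genes had 0 past the threshold adjusted over the list alone. Camera at median 0.20 gave adjusted p = 0.00123, and adjusted p = 0.19 with an estimated correlation. Proliferation genes had 0 past the threshold adjusted over the list alone. At median 0.12, camera gave adjusted p = 0.00494 and adjusted p = 0.892 with an estimated correlation. Without PSmut 1 or 2, RBPjmut 4 or the library labelled RBPjmut 3, this call was lost (adjusted p up to 0.903). The median was 0.06 without PSmut 1, 0.08 without PSmut 2, 0.23 without PSmut 4, 0.21 without RBPjmut 1, 0.25 without RBPjmut 2, 0.02 without the library labelled RBPjmut 3 and 0.05 without RBPjmut 4. With the 8 high-Xist arrays alone the proliferation list was called in the opposite direction (median -0.28, adjusted p = 0.00259). Over all its alternatives adjusted p ranged from 1.87e-06 to 0.921. Spinous keratinocyte genes had 2 lower adjusted over the list alone. Median -0.22 gave camera adjusted p = 0.000122, and adjusted p = 0.188 with an estimated correlation. The median was -0.37 without RBPjmut 2. Granular and cornified layer genes had 2 lower and 1 higher adjusted over the list alone. With median -0.19, camera gave adjusted p = 0.000106, and adjusted p = 0.479 with an estimated correlation. The median was -0.32 without PSmut 3, -0.35 without RBPjmut 2 and -0.09 without the library labelled RBPjmut 3. Barrier-lipid genes had 0 past the threshold adjusted over the list alone. Camera at median -0.26 gave adjusted p = 0.000153, and adjusted p = 0.0848 with an estimated correlation. Hair shaft genes had 0 past the threshold adjusted over the list alone. At median -0.40, camera gave adjusted p = 0.000153 and adjusted p = 0.698 with an estimated correlation. Without PSmut 3 or the library labelled RBPjmut 3, this call was lost (adjusted p up to 0.311). The median was -0.19 without PSmut 3, -0.69 without RBPjmut 2 and -0.14 without the library labelled RBPjmut 3. Melanocyte genes had 0 past the threshold adjusted over the list alone. Median -0.29 gave camera adjusted p = 0.00494, and adjusted p = 0.487 with an estimated correlation. Adjusted p reached 0.0936 and the call was lost without PSmut 3 or 4, RBPjmut 1 or the library labelled RBPjmut 3. The median was -0.19 without PSmut 3.

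The interaction asks whether the change in PSRmut skin equals the sum of the changes of the single lesions on the log2 scale. It is negative where PSRmut was lower than that sum. Among the 41 genes past the threshold, those furthest below the sum included Sprr2g at -4.42 (SE 0.72, adjusted p = 0.0151), Epgn at -3.28 (SE 0.49, adjusted p = 0.00869) and Ms4a10 at -3.01 (SE 0.37, adjusted p = 0.0047). The call of Sprr2g was lost without background correction (-2.72, adjusted p = 0.0652). Krtap1-5 was at -3.21 (SE 0.56, adjusted p = 0.0189). Krtap1-5 no longer passed without WT 2 or PSmut 2 (adjusted p up to 0.0591). Furthest above it among these were Abra at 2.34 (SE 0.39, adjusted p = 0.0158), Btc at 1.63 (adjusted p = 0.0428), Commd2 at 1.61 (adjusted p = 0.0252) and Cyp2b19 at 1.61 (adjusted p = 0.0345). Btc no longer passed without any WT array, PSmut 2, 3 or 4, RBPjmut 4, the library labelled RBPjmut 3 or any PSRmut array (adjusted p up to 0.0939). Commd2 no longer passed without WT 1, 2 or 3, PSmut 2, RBPjmut 4, the library labelled RBPjmut 3 or PSRmut 4 (adjusted p up to 0.0673). Cyp2b19 no longer passed without WT 1, 2 or 3, PSmut 1, 2 or 4, RBPjmut 1 or 4, the library labelled RBPjmut 3 or PSRmut 3 or 4 (adjusted p up to 0.0921). Other alternatives set beforehand also ended the calls of Btc (0.0894) and Cyp2b19 (0.07), adjusted p up to the value in brackets. Commd2 was above background on 2 PSmut, 1 RBPjmut and 3 PSRmut arrays, and another of its probes read 0.12, 0.02 and -0.17 against WT in the 3 groups. All 41 genes with an interaction had the same direction in the 3 comparisons with WT, and 32 had passed in all 3. Selection favours such a shared direction, because the interaction and the 3 comparisons hold the same WT mean. Their median change in that direction was 1.25 in PSmut, 1.08 in RBPjmut and 1.03 in PSRmut skin. The sum of the single lesions was 2.40.

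Of the lists, 11 were called for the interaction. None of these calls held with an estimated correlation, and the directional test of fry called 1, the barrier lipids. Hair shaft genes had 3 of 27 lower, and 19 lower adjusted over the list alone. With median -1.74, camera gave adjusted p = 4.17e-19, and adjusted p = 0.286 with an estimated correlation. Stress and alarmin genes had 0 of 23 past the threshold, and 10 lower adjusted over the list alone. Camera at median -1.02 gave adjusted p = 5.83e-09, and adjusted p = 0.189 with an estimated correlation. Barrier-lipid genes had 0 of 15 past the threshold, and 1 higher adjusted over the list alone. At median 0.44, camera gave adjusted p = 0.000185 and adjusted p = 0.152 with an estimated correlation. Dermal genes had 1 of 23 higher, and 3 higher adjusted over the list alone. Median 0.32 gave camera adjusted p = 0.000595, and adjusted p = 0.547 with an estimated correlation. Vascular genes had 0 of 20 past the threshold, and 3 higher adjusted over the list alone. With median 0.39, camera gave adjusted p = 0.00082, and adjusted p = 0.42 with an estimated correlation. Basal keratinocyte genes had 0 of 15 past the threshold, and 2 lower adjusted over the list alone. Camera at median -0.27 gave adjusted p = 0.0362, and adjusted p = 0.424 with an estimated correlation. Adjusted p reached 0.128 and the call was lost without WT 3, PSmut 3 or 4, RBPjmut 4, the library labelled RBPjmut 3 or PSRmut 2. The median was -0.16 without PSmut 4. Interferon-stimulated genes had 0 of 19 past the threshold, and 0 adjusted over the list alone. At median -0.25, camera gave adjusted p = 0.0362 and adjusted p = 0.599 with an estimated correlation. Without WT 2, PSmut 4, RBPjmut 1 or 4, the library labelled RBPjmut 3 or PSRmut 4, this call was lost (adjusted p up to 0.232). The median was -0.39 without PSmut 3, -0.41 without RBPjmut 2 and -0.13 without PSRmut 4. Muscle genes had 0 of 25 past the threshold, and 1 higher adjusted over the list alone. Median 0.20 gave camera adjusted p = 0.0461, and adjusted p = 0.604 with an estimated correlation. Adjusted p reached 0.259 and the call was lost without WT 1 or 2, PSmut 3, RBPjmut 1, the library labelled RBPjmut 3, PSRmut 3 or the library labelled PSRmut 1. The median was 0.12 without WT 2 and 0.11 without PSmut 3. Melanocyte genes had 0 of 10 past the threshold, and 1 lower adjusted over the list alone. With median -0.37, camera gave adjusted p = 0.0362, and adjusted p = 0.547 with an estimated correlation. Without WT 2, PSmut 1 or 2, RBPjmut 1, the library labelled RBPjmut 3 or PSRmut 2 or 4, this call was lost (adjusted p up to 0.103). The median was -0.24 without WT 2. Schwann cell genes had 0 of 10 past the threshold, and 1 higher adjusted over the list alone. Camera at median 0.35 gave adjusted p = 0.0392, and adjusted p = 0.42 with an estimated correlation. Adjusted p reached 0.105 and the call was lost without WT 2 or 4, PSmut 1 or 4, RBPjmut 2, the library labelled RBPjmut 3, PSRmut 2 or 3 or the library labelled PSRmut 1. The median was 0.22 without PSmut 1. Neutrophil genes had 0 of 9 past the threshold, and 0 adjusted over the list alone. At median -0.22, camera gave adjusted p = 0.0392 and adjusted p = 0.42 with an estimated correlation. Without WT 1 or 3, PSmut 3 or 4, the library labelled RBPjmut 3, PSRmut 3 or 4 or the library labelled PSRmut 1, this call was lost (adjusted p up to 0.124). The median was -0.35 without WT 3, -0.33 without WT 4 and -0.36 without PSRmut 2.

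For the interaction limma called 41 genes, 25 above and 16 below the sum, of which 18 and 16 were at least 2-fold. An unadjusted p under 0.05 was reached by 1195. Median scaling called 38 genes, 44.7% of them above the sum where quantile normalization gave 61.0%. The count was 14 without WT 1, 16 without WT 2, 24 without WT 3, 21 without PSmut 1 and 17 without PSmut 2. It was 25 without RBPjmut 1, 132 without RBPjmut 2, 20 without the library labelled RBPjmut 3 and 20 without RBPjmut 4. It was 22 without PSRmut 2 and 20 without PSRmut 4. PSmut 4, the library labelled RBPjmut 3, PSRmut 2 and PSRmut 3 stood together at 16.6 to 21.9 on the second principal component, where the other mutant arrays lay at -23.7 to 4.86. Without these 4 the count was 5. Array weights gave 349 and the Y-linked mean as covariate 27. Of the alternatives chosen after the data were seen, Ddx3y as covariate gave 22 and the 8 high-Xist arrays alone 2. Without WT 1 and WT 2 together it was 0, without WT 3 and WT 4 together 27, and without the libraries labelled RBPjmut 3 and PSRmut 1 20.

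Because the mice were of mixed genetic background, genes near the targeted loci were tested for an excess of calls. Of 9112 tested genes with a position in the files, 189 lay within 10 Mb of a probe for Psen1, Psen2 or Rbpj. Near the loci 6, 5 and 4 genes (3.18, 2.65 and 2.12%) passed the threshold in PSmut, RBPjmut and PSRmut skin. Far from them 3.22, 2.91 and 2.77% passed (Fisher's exact test, two-sided, p = 1, 1 and 0.821, adjusted p = 1 in each case for 4 tests). For the interaction 2 genes (1.06%) passed near the loci and 0.370% far from them (exact p = 0.164, adjusted p = 0.654).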

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

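The tests on the sex of the pups for the 559 genes and on the arrays that stand apart for Psen1 were chosen only after their results were seen, and the other tests of explanations were set before theirs.

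Of 35 splits of 8 arrays into 4 and 4, only the real one reached 346, 318 and 294 genes in PSmut, RBPjmut and PSRmut. The highest other splits gave 0, 1 and 1 genes past the threshold. This argues against chance division, with 1 in 35 the least possible. For the interaction 1 of 100 drawn splits reached the real 41 genes, the highest other 12. This does not separate the interaction from WT against all mutants. Between mutants the real count was 0 in each of the 3 pairs, which all 35 splits reach, so this test says nothing there. The highest other splits gave 367 genes for PSRmut and PSmut (PSmut 1, PSmut 2, the library labelled PSRmut 1 and PSRmut 4 against the rest), 519 for PSRmut and RBPjmut (RBPjmut 1, the library labelled RBPjmut 3, PSRmut 2 and PSRmut 3 against the rest) and 1 for PSmut and RBPjmut. The first 2 point to a structure of the samples other than the labelled groups.

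The first pattern weighed was the 559 genes past the threshold in at least 1 comparison with WT, since all 4 WT arrays had high Xist and 8 mutant arrays did not. In the direction found, the 4 mutant arrays with high Xist differed from WT by a median of 0.63 (0.57 to 0.71 per array). The 8 other mutant arrays differed by 0.64. All 559 genes kept direction in the 4, but were chosen with these arrays, so the sex of the pups stays open. The medians against a pair of WT arrays alone were 0.58 and 0.70. Both pairs served to choose the genes, so a close pair stays open too. Loss of presenilins or RBPj is the explanation the design names and may account for the set, as a hypothesis found and tested on the same data. Differences in litter or genetic background between genotypes stay open and were not tested beyond the windows around the targeted loci.

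A second pattern was the interaction, a difference between the effect of RBPj loss with and without presenilins that passed its own test. It was 2.34 for Abra, 1.63 for Btc, 1.61 for Commd2, 1.61 for Cyp2b19, -4.42 for Sprr2g, -3.28 for Epgn, -3.21 for Krtap1-5 and -3.01 for Ms4a10. List medians were -0.27 for basal, 0.44 for barrier-lipid, -1.74 for hair shaft, -1.02 for alarmin, -0.25 for interferon-stimulated, 0.32 for dermal, 0.20 for muscle, 0.39 for vascular, -0.37 for melanocyte, 0.35 for Schwann cell and -0.22 for neutrophil genes, and none of these list calls held with an estimated correlation. Without 1 array, medians that moved by over 1.5 times were basal -0.16 without PSmut 4; interferon -0.39 without PSmut 3, -0.41 without RBPjmut 2 and -0.13 without PSRmut 4; muscle 0.12 without WT 2 and 0.11 without PSmut 3; melanocyte -0.24 without WT 2; Schwann cell 0.22 without PSmut 1; neutrophil -0.35 without WT 3, -0.33 without WT 4 and -0.36 without PSRmut 2.

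Of the 41 interaction genes 0 lay at the signal's floor or ceiling in all mutant groups, which argues against signal limits. Their median interaction was 1.42 with Ddx3y as covariate, 1.41 without, and at least 1.37 without either close WT pair. They were chosen with these arrays, so sex and a WT pair stay open. That both lesions act through the same pathway, so that a second lesion adds little, is a hypothesis that was not tested and stays open. The shared direction of these genes against WT is no evidence for it, since the interaction by which they were selected holds the same WT mean.

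The third pattern was the Psen1 level of the library labelled PSRmut 1 (8.12) against 7.07 to 7.19 on the other PSRmut arrays, which stood far from its group, and of the library labelled RBPjmut 3 (7.19) against 8.01 to 8.22. With the labels of these arrays exchanged, 208 genes passed the threshold between PSRmut and RBPjmut, while 0 of the other 15 exchanges of 1 array of each group reached as many and the highest gave 3. The count is over all genes, and Psen1, which picked the arrays, is no evidence. An exchange may account for both levels, but not for WT 1 (7.38), within the PSmut range. A structure of the arrays outside the genotypes cannot be told apart from it: over the 8 mutant arrays outside the group of 4 on component 2, Psen1 and component 2 had r = -0.628 (exact permutation p = 0.0821, adjusted p = 0.164 for 2 tests), Spearman's rho -0.381 (exact permutation p = 0.36), and r = -0.397 without the 2 arrays farthest on component 2. The labels were kept as deposited, and both explanations stay open.

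Single arrays stood far from the other 3 of their group in 26 of 376 sets of 4 values tested, where chance alone gives about 18.8 (1 in 20), and 7 of the 26 were in RBPjmut 2 and 4 in the library labelled PSRmut 1. In RBPjmut 2 these were Krt6b (log2 value 5.62), Sprr4 (6.05), Casp14 (11.99), Cyp4f39 (8.37), LOC100039728 (8.72) and the scores of interferon-stimulated (-0.34) and melanocyte genes (0.11). In the library labelled PSRmut 1 they were Psen1, Kif11 (7.20), Ddx3y (4.82) and the Y-linked score (-0.22). Others were Casp14 (11.50) and Cd3e (5.01) in PSmut 1, the interferon (0.081) and muscle scores (-0.56) in PSmut 3, Krt84 (5.04) and the immediate early score (0.97) in PSmut 4, Ddx3y (5.01) and the Y-linked score (-0.30) in RBPjmut 1, S100a9 (8.43) in the library labelled RBPjmut 3, Tslp (6.36) in PSRmut 2, S100a8 (10.42) in PSRmut 4, Trib3 (8.10) and Bbox1 (8.57) in WT 1, Cldn5 (11.15) in WT 2 and the Wnt score (0.046) in WT 4.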

How the results depend on the processing

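The alternatives with Ddx3y as covariate, with the 8 high-Xist arrays alone, and without sets of arrays (PSmut 4, RBPjmut 3, PSRmut 2 and PSRmut 3; WT 1 and 2; WT 3 and 4; RBPjmut 3 and PSRmut 1) were chosen after seeing the data, the others before. Of 1318 values of named genes past the threshold in their comparison, under the alternatives set beforehand, 1216 kept direction and side of the threshold and 102 were weaker, apart from single-array omissions; of 666 under the added ones 414 kept both and 252 did not. For called lists these were 744 the same and 154 weaker of 898, and 283 the same, 105 weaker and 2 reversed of 390. Without 1 array, 1546 of 1776 values of such genes and 932 of 1040 list values kept direction and call. Main counts of genes were 346, 318, 294, 0, 0, 0 and 41 for PSmut, RBPjmut and PSRmut against WT, PSRmut against PSmut, PSRmut against RBPjmut, PSmut against RBPjmut, and the interaction, and main counts of lists 12, 12, 15, 4, 2, 9 and 11. Where a value moved below, the cause was not tested, except that settings with fewer arrays have less power.

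Leaving out each array in turn gave 167 to 475 genes in PSmut, 98 to 519 in RBPjmut, 112 to 373 in PSRmut skin, 14 to 132 for the interaction and 0 throughout between mutants. The lists called were 10 to 13, 7 to 14 and 12 to 17 against WT, 2 to 7, 2 to 9 and 6 to 11 between mutants in the same order, and 6 to 12 for the interaction. Array weights called 1303, 947 and 945 genes against WT and 349 for the interaction, and the trended and robust variance 2 between PSmut and RBPjmut. With the Y-linked mean as covariate 94 passed in RBPjmut, 102 in PSRmut and 27 in the interaction, and with Ddx3y 97, 115 and 22. The high-Xist arrays alone, where RBPjmut and PSRmut keep 1 array each that is assumed to vary like the other groups, gave 30 genes in RBPjmut, 1, 1 and 3 between mutants and 2 for the interaction. The interaction had 5 genes without the 4 arrays at one end of component 2. Without WT 1 and WT 2 the counts were 71, 27 and 46 and 0 for the interaction, and without WT 3 and WT 4 203, 161, 168 and 27. Without RBPjmut 3 and PSRmut 1 they were 3, 1 and 3 between mutants and 20 for the interaction.

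Lists called for PSRmut against RBPjmut were 4 without background correction, 4 with an offset of 50, 8 with median scaling (9 for PSRmut against PSmut), 7 with every probe by itself, 10 with the high-Xist arrays (14 for PSmut against RBPjmut) and 4 without the 4 arrays of component 2. Without a filter 1 list was called for PSRmut against PSmut and 7 for the interaction. Without WT 1 and WT 2 there were 9 in PSRmut and 6 for the interaction, and without RBPjmut 3 and PSRmut 1 there were 7 in RBPjmut, 7 for PSRmut against PSmut, 1 for PSRmut against RBPjmut and 5 for the interaction. Camera with an estimated correlation called 3, 0 and 2 lists against WT and 0, 0, 0 and 0 otherwise, and directional fry 6, 8 and 8, then 0, 0, 0 and 1. Mixed fry, which asks another question, passed for 24, 21 and 17, then 0, 0, 3 and 11.

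Values that changed sign were these. Psen1 in RBPjmut was 0.11 with the Y-linked mean, 0.11 with Ddx3y, 0.24 with high-Xist arrays, 0.12 without the 4 arrays, 0.16 without WT 3 and WT 4, 0.12 without RBPjmut 3 and PSRmut 1, 0.02 without WT 3 and 0.12 without RBPjmut 3, within -0.306 to 0.12 without 1 array. Psen1 in PSRmut was 0.14, Psen2 in PSmut -0.14, Shh in PSRmut -0.42, Ddx3y in PSRmut -0.96, the Wnt list in PSRmut -0.061 and the proliferation list between PSmut and RBPjmut -0.28 with the high-Xist arrays, the last called in the opposite direction (adjusted p = 0.00259, 1.87e-06 to 0.921 over its alternatives). Psen2 in PSRmut was -0.02 with median scaling, and in PSmut it ranged from -0.024 (without PSmut 1) to 0.304 without 1 array. Shh in PSRmut was -0.074 without the 4 arrays, and Ddx3y in PSRmut -0.34 with the Y-linked mean, from which it is computed.

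With the replicate number as a block 262, 242, 198 and 44 genes passed against WT and for the interaction and 0 between mutants. Residuals of arrays with the same number correlated at -0.25 to 0.49 (mean -0.01, 4 of 24 over 0.1) and of different numbers at -0.44 to 0.56 (mean 0.00, 15 of 72 over 0.1), so the numbers were taken to share only a name. The windows of 5 and 20 Mb around the loci gave 1 exact p under 0.05 of 8, 0.0475 for the interaction at 20 Mb (Fisher's exact test, adjusted p = 0.19 of 4 tests). The series values were not run apart, since they equal the authors' table, the slide was not run as a block, since no header names it, and the interaction could not be fitted with only the groups compared. About 50% of probes lay at background, Rbpj among them, and a change in such a gene was not measurable here.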

Other observations

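Adipocyte genes had 1 of 16 measured members past the threshold in PSmut and in PSRmut skin, Thrsp, a regulator of lipogenesis, at -1.25 and -0.99 (limma adjusted p = 0.0105 and 0.0456, the latter lost without WT 1, 2 or 4, PSmut 2 or 3, RBPjmut 1 or 4, PSRmut 2 or 3 or the library labelled PSRmut 1, adjusted p up to 0.151), while the list medians were 0.22, 0.16 and 0.18 in PSmut, RBPjmut and PSRmut skin. Proliferation genes had 0, 1 and 0 of 26 past the threshold, the mitotic kinesin Kif11 at -0.88 in RBPjmut skin (adjusted p = 0.0285, lost without WT 1 or 2, RBPjmut 4 or the library labelled RBPjmut 3, adjusted p up to 0.0892). Pthlh, the parathyroid hormone-related peptide in the outer root sheath list, rose by 1.04, 1.05 and 0.91 (adjusted p = 0.011, 0.0155 and 0.029). That call was lost without WT 1, adjusted p up to 0.05 in PSmut, lost without WT 1 or RBPjmut 1, adjusted p up to 0.063 in RBPjmut, and lost without WT 1, 2 or 4 or PSRmut 2 or 3, adjusted p up to 0.113 in PSRmut skin. Other alternatives also ended the PSRmut calls of Thrsp (0.116) and Pthlh (0.147) and the RBPjmut calls of Kif11 (0.104) and Pthlh (0.0751), with adjusted p up to the values in brackets.

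The adipocyte score minus the vascular score was 0.389 higher on the 12 mutant arrays than on the 4 WT arrays (exact permutation p = 0.0566, two-sided), with an SD of 0.353 among mutant and 0.174 among WT arrays, a comparison chosen after the lists had been seen.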
